A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

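RNA from Saccharomyces cerevisiae strain BY4741, a MATa strain, was measured on 4 Affymetrix yeast arrays. Per the labels, cells grew in rich medium at 30 °C to an OD600 of 0.5 and received 2 mM DTT, or water as control, for 1 h; cycloheximide at 0.1 mg/mL then stalled ribosomes, and lysates ran on sucrose gradients of 15 to 60%. Per the series design and the labels, gradient fractions were joined into a sub-polysomal and a polysomal sample, RNA of 3 extracts per treatment was pooled, and 5 µg of RNA was labelled with biotin for each array. Buffers for lysis and gradients held 0.5 mM DTT in both treatments, per the labels. The chip type was read from the run sheets of the arrays. These sheets also show that each array had its own wash module and scan, so array run and group cannot be told apart. The labels give the strain as carrying a deletion of met5; MET5 and MET17 were both read out for that reason.

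The deposited values are linear intensities, 1 per probe set and array, that the authors scaled per array: after 2% of probe sets is trimmed from each end, the mean of every array is about 100 (100.1 on each). The algorithm that summarised probes into these intensities is not given in the sources used here. The table holds 9335 probe sets, with 0 zeros on the control sub-polysomal array, 9 on the control polysomal, 11 on the DTT sub-polysomal and 26 on the DTT polysomal array. All 4 columns belong to a sample, and 0 columns lack one. Detection calls were not used here. The run sheets hold no measurement per gene and were read for the chip type and run settings only.

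Probe sets were matched to genes through a table of the genes of each probe set, and symbols were taken from a gene table of assembly R64, used for names only. Of 9335 probe sets, 60 are controls, 6832 carry a gene, 6504 name 1 gene, 328 name several genes and 2443 name none. The 6504 were matched by gene ID to 5656 genes, and 0 symbols changed. Probe sets naming several genes or none were left out of gene values.

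Gene values were made as follows. Each array's floor was its 40th percentile over all probe sets (28.2, 17.6, 22.6 and 15.9 for control sub-polysomal, control polysomal, DTT sub-polysomal and DTT polysomal RNA), and a probe set was measured when it lay above the floor on all 4 arrays. Intensities were taken to log2, each array was centred on the median of the 4720 measured probe sets that are not controls, and a gene's value is the mean of its measured probe sets. This left 3923 genes, 161 of them with several measured probe sets and 115 with no probe set of the plain kind; 3085 lay above every array's median. The median intensity was 40.5, 28.5, 36.7 and 26.8 in the order above, which sets how far most genes lie over the floor.

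Samples were grouped by treatment and fraction, as their titles give them. The quantities are the log2 ratio of polysomal to sub-polysomal RNA in control and in DTT-treated cells, the difference of these ratios (DTT minus control, called the change in polysome association), and the log2 ratio of DTT to control in each fraction. Because RNA of each fraction was labelled separately, all ratios are relative to the median of the measured probe sets, which need not be the median gene. Each group holds 1 array and so gives no spread between replicates; no p-value was computed and genes were counted past a 2-fold limit. As a technical yardstick, the pooled SD between probe sets of the same gene was computed over 161 genes and 397 probe sets, and the number of genes that a normal spread of that SD around the all-gene median would put past the limit was set beside each count. That SD covers differences between probe sets on the same arrays, not differences between cultures, extracts or hybridisations.

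A set of 37 gene lists was fixed from general knowledge before the data were examined, together with the comparisons, the limits, the alternatives to try and the rule for named genes. Each list with at least 4 measured genes (34 lists) was described by its median for 5 quantities (170 medians) and by the percentile of that median among 10000 random lists of the same size, matched on mean log2 value in 20 bins. Random lists were drawn from all measured genes, members of the list included. The percentile describes these arrays and does not treat genes as replicates. The lists were ER chaperones and folding enzymes, ER-associated degradation, ER translocation and signal peptidase, N-glycosylation, ER to Golgi transport, O-mannosylation, transport to the plasma membrane, unfolded protein response signalling, cytosolic and mitochondrial ribosomal proteins, ribosome biogenesis, translation initiation, elongation and termination, aminoacyl-tRNA synthetases, Gcn4-controlled amino acid synthesis, sulphur amino acids, thiol redox defence, cytosolic chaperones, stress-induced carbohydrate metabolism, cell wall, phospholipid and inositol, sterol and sphingolipid, fatty acid, glycolysis, respiration, proteasome, core histones, vacuole, autophagy, iron and zinc uptake, transcripts with upstream open reading frames, structured RNAs, tRNA splicing and mRNA decay, mating type a, mating type alpha, meiosis and auxotrophic markers.

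The rule for named genes takes genes above every array's median: the 12 largest increases and decreases in polysome association past 2-fold, the 8 highest and 8 lowest control ratios, and the 12 highest and 12 lowest with DTT by the smaller change of the fractions. It adds 22 genes fixed in advance, whatever their values, and up to 2 members at each end of a list. Genes behind small counts that fall outside the rule were chosen after their values were seen, and the text says so where they appear.

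Alternatives changed 1 choice at a time: no centring, quantile normalization, loess on the mean value (span 0.4), a floor at the 25th or 60th percentile, no floor, a floor in 1 fraction of each treatment, an offset of each array's 10th percentile, plain probe sets only, the brightest probe set of a gene, limits of 1.5-fold and 3-fold, the mean of a list in place of its median, and unmatched random lists. Centring on the measured genes and on 9 hybridisation control probe sets was added after the data were seen. The closing section gives their effect. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

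The steps were tested on simulated data with noise of SD 0.216 per array. For the change in polysome association, 4235 genes were in the step, and shares are of the changed genes still measured. A change of 1.5 put in was called in 92.0% of 50 genes and one of -1.5 in 85.3% of 34. Changes of 2.5 and -2.5 were called in 100% of 49 and of 16 genes, and 1.9% of 4069 unchanged genes were called. Each change was put into 50 genes, so most genes with a loss of 2.5 fell to the floor and were not scored. An ER chaperone list shifted by 0.5 came out at percentile 99.8, and 1 of 33 unshifted lists fell outside.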

Results

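The question behind these arrays is which yeast transcripts move onto or off ribosomes during the unfolded protein response, here set off by dithiothreitol (DTT), a reductant that keeps proteins in the endoplasmic reticulum (ER) from forming disulphide bonds. Growing cells took 2 mM DTT or water for 1 h, ribosomes were stalled with cycloheximide, and lysates were parted on a sucrose gradient into sub-polysomal RNA, which carries few or no ribosomes, and polysomal RNA. The 4 groups were control sub-polysomal, control polysomal, DTT sub-polysomal and DTT polysomal RNA, with 1 array each (n = 1, RNA of 3 extracts pooled). With 1 array per group no difference could be tested against replicates, which limits the precision of every value for a single gene. The only error at hand is the spread between probe sets of the same gene, with an SD (log2) of 0.45 for DTT against control in sub-polysomal RNA, 0.41 in polysomal RNA, 0.41 for the polysomal to sub-polysomal ratio in control cells, 0.32 in DTT-treated cells and 0.43 for the difference of these ratios. Values are log2 differences between arrays, each array centred on its median, for 3923 genes above the floor on all 4 arrays. Gene groups were set against 10000 random lists of the same size and brightness, and a group is called outside when its median lay beyond the range that holds 95% of their medians.

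The control sub-polysomal array stood apart from the other arrays. Its rank correlation over probe sets was between 0.885 and 0.920 in its 3 pairs, and between 0.922 and 0.959 in the pairs without it. Its brightest probe set read 17315 against 4855 to 8074 elsewhere, and its 100 brightest probe sets held 32.8% of the summed intensity against 20.0 to 26.0%. The 3' probe set of the actin gene ACT1 read 2.49 times its 5' probe set there, 1.91 times on the DTT sub-polysomal array and 1.52 and 1.48 times on the polysomal arrays. For the TATA-binding protein gene SPT15 that ratio was 4.41 and 4.83 in sub-polysomal RNA and 3.11 and 3.12 in polysomal RNA. Every control ratio, every change in polysome association and every sub-polysomal change with DTT uses that array. The polysomal change with DTT and the ratio within DTT-treated cells do not.

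Does DTT change how much of a transcript there is? Transcripts for ER chaperones and for transport from the ER to the Golgi were higher with DTT in both RNA fractions, and so were those of HAC1, which encodes the transcription factor of the unfolded protein response, and of the cell wall stress kinase SLT2. Transcripts for building ribosomes, for mitochondrial respiration and for the a mating type were lower in both. The change was largely shared by the fractions: 111 genes were at least 2-fold higher in both and 181 at least 2-fold lower in both, and 0 were 2-fold higher in 1 fraction and 2-fold lower in the other. Across genes the changes correlated with Pearson r 0.770 and Spearman rho 0.726, although genes are not independent replicates. No array of total RNA is part of this comparison, so a change seen in both fractions stands in for a change of transcript level.

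In polysomal RNA 170 genes were 2-fold higher and 276 lower with DTT, against 13.3 and 53.6 from the spread between probe sets around the all-gene median. In sub-polysomal RNA the counts were 223 and 437, against 15.5 and 146.5. The excess on the lower side of these yardsticks comes from all-gene medians below 0. Under loess scaling, which removes a trend with brightness, the balance turned to the higher side, with 331 genes 2-fold higher and 195 lower in sub-polysomal RNA and 142 and 111 in both fractions. It also turned with no floor in sub-polysomal RNA (634 and 561), and when centred on the hybridisation controls in polysomal RNA (292 and 164) and in both fractions (149 and 115). At a 3-fold limit it turned in polysomal RNA (68 and 61) and in both fractions (44 and 35). The all-gene median was -0.20 in sub-polysomal and -0.10 in polysomal RNA; it was -0.095 in sub-polysomal RNA without centring, -0.0010 and 0.017 under loess scaling, and 0.14 in polysomal RNA when centred on the hybridisation controls. The random lists carry the same shift as the gene groups set against them.

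The ER chaperones and folding enzymes were higher in both fractions. Their median was 0.92 in sub-polysomal RNA (1.89-fold higher) and 0.49 in polysomal RNA, above all 10000 matched random lists and at percentile 99.95. In each fraction 7 of 17 members were at least 2-fold higher, 5 of them in both, and 0 were 2-fold lower. The highest were SIL1, the nucleotide exchange factor of the ER chaperone Kar2 (4.53-fold in sub-polysomal and 6.06-fold in polysomal RNA), the proline isomerase gene FPR2 (4.88-fold and 3.59-fold) and ERO1, the oxidase that makes disulphide bonds in the ER (2.28-fold and 5.67-fold). The lumenal Hsp70 gene LHS1 had log2 changes of 1.72 and 1.84 in the sub-polysomal and polysomal fraction, and the disulphide isomerase gene EUG1 1.53 and 1.75. KAR2, for the main Hsp70 of the ER, had changes of 0.92 and 0.76, its isomerase partner PDI1 0.64 and 0.46 and the co-chaperone gene SCJ1 0.44 and 1.13. The calnexin gene CNE1 lay at the other end (-0.64 and -0.42).

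**Figure D1:**
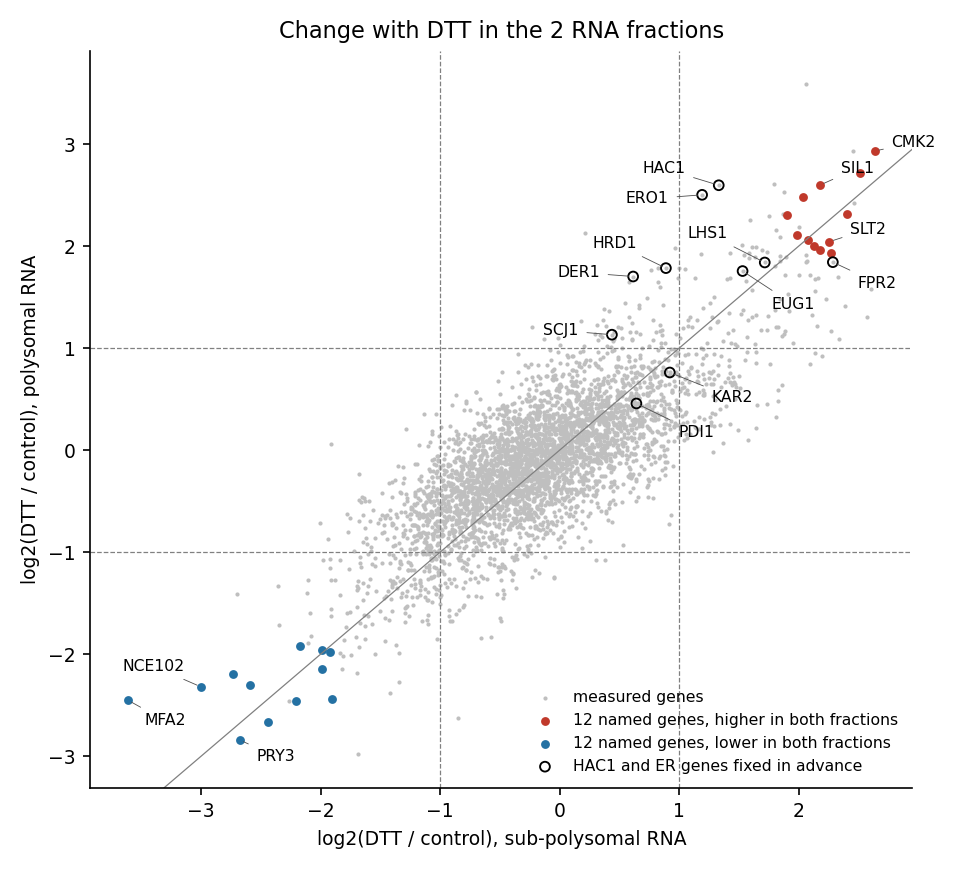
Each grey point is 1 of 3923 genes, with the log2 change with DTT in sub-polysomal RNA on the horizontal axis and in polysomal RNA on the vertical axis; red and blue points are the 12 named genes highest and lowest in both fractions, open circles HAC1 and ER genes fixed in advance, dashed lines 2-fold and the solid line equal change. Points follow the diagonal (Pearson r 0.770 across genes), and HAC1 (1.33 and 2.60) and ERO1 (1.19 and 2.50) lie above it.

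Other steps of the secretory pathway had medians above 0 in both fractions. Genes of ER-associated degradation, which send misfolded proteins to the proteasome, had a median of 0.36 in sub-polysomal RNA (at percentile 98.1) and 0.38 in polysomal RNA (at percentile 99.35). There 2 and 3 of 14 members were 2-fold higher, with the ubiquitin ligase gene HRD1 at 0.89 and 1.78 and the membrane protein gene DER1 at 0.61 and 1.70. With no floor the sub-polysomal value of DER1 was 3.03. The sub-polysomal call of the group ended under loess scaling and with plain probe sets only. Genes of ER translocation and signal peptidase were outside in polysomal RNA (0.60, above all 10000 matched random lists, 5 of 19 2-fold higher, among them the translocon genes SEC66 at 1.27 and SEC72 at 1.21). In sub-polysomal RNA their median was 0.18 (at percentile 96.3), and with a floor at the 60th percentile the polysomal call ended. N-glycosylation genes had a polysomal median of 0.27 (at percentile 99.88; 2 of 27 2-fold higher, GFA1 of amino sugar synthesis at 1.04 and the mannosyltransferase gene ALG12 at 1.03) and a sub-polysomal median of 0.11, inside the random range. ER to Golgi vesicle transport stood at 0.30 and 0.33 (at percentile 99.91 and above all 10000 matched random lists), with 5 and 3 of 32 genes 2-fold higher and 3 and 0 lower; the coat adaptor gene SFB3 (1.59 and 1.93) and the cargo receptor gene ERV29 (1.84 and 1.48) led. Protein O-mannosylation was outside in sub-polysomal RNA (0.40, at percentile 99.26, 2 of 13 2-fold higher, PMT3 at 1.69 and KTR1 at 1.32) and inside in polysomal RNA (0.063).

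HAC1, the transcript that the ER stress sensor Ire1 splices, was 2.52-fold higher in sub-polysomal and 6.05-fold higher in polysomal RNA, the latter with a log2 change of 1.93 in place of 2.60 when no floor was set. The group of unfolded protein response signalling genes had medians of 0.84 and 1.01 (percentiles 98.9 and 99.79), with HAC1 and SLT2 the 2 of 4 members at least 2-fold higher. The call ended in 3 of the settings for the floor. IRE1 itself was above the floor on 1 array only (25.3, 12.0, 21.7 and 18.5 in control sub-polysomal, control polysomal, DTT sub-polysomal and DTT polysomal RNA). INO1, the inositol synthesis gene that the pathway can switch on, read 4.3, 11.0, 31.1 and 19.1 in the same order, above the floor on the DTT arrays only. The stress-responsive transcription factor gene GCN4 stood at -0.27 and -0.12, with signs that flipped under loess scaling in both fractions, under quantile scaling in sub-polysomal RNA and under hybridisation control scaling in polysomal RNA.

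Among genes above every array's median, the 12 highest in both fractions had varied functions. They were led by CMK2, a calmodulin-dependent kinase gene (2.64 and 2.93), and NFG1, which encodes a regulator of filamentous growth (2.51 and 2.72). SIL1 and SLT2, the kinase of the cell wall integrity pathway (2.26 and 2.04), followed with MET14, which activates sulphate for methionine synthesis (2.13 and 2.00), COS4 of the family that sorts membrane proteins for turnover (2.08 and 2.06), SCS3 of ER lipid storage (1.99 and 2.11), the desiccation tolerance gene STF2 (2.18 and 1.96), the protease inhibitor-like gene YHR138C (2.27 and 1.93) and TOS3, a kinase gene upstream of Snf1 (1.91 and 2.31). The open reading frames YER138W-A (2.41 and 2.31) and YOR385W (2.04 and 2.48) have no well known function. COS4 and YER138W-A were each read by 1 probe set that is not of the plain kind, so other transcripts may add to their values.

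Sulphur and redox genes were modestly higher as groups. Sulphur amino acid genes had medians of 0.19 and 0.36 (percentiles 98.1 and 99.98), with 4 and 3 of 23 2-fold higher, MET14 and the sulphurylase gene MET3 (1.98) first in polysomal RNA; this call ended with a floor at the 60th percentile. Thiol redox and oxidative defence genes stood at 0.14 and 0.28 (percentiles 97.9 and 99.92), with 4 and 1 of 27 members 2-fold higher, such as the glutathione transferase gene GTT1 (1.86 in sub-polysomal RNA) and the thioredoxin gene TRX2 (1.02 in polysomal RNA). Proteasome subunits had medians of 0.23 and 0.16 (percentiles 99.50 and 98.7), with 1 of 34 2-fold higher in each, RPN10 (1.26) in sub-polysomal and RPN1 (1.17) in polysomal RNA; the polysomal call ended with a floor at the 60th percentile and with no floor. Stress-induced carbohydrate genes were outside in polysomal RNA (0.26, at percentile 99.64, 4 of 21 2-fold higher, led by the glycerol synthesis genes GPP2 at 1.34 and GPD1 at 1.31) and inside in sub-polysomal RNA (0.090).

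Genes for making ribosomes were lower as groups. Ribosome biogenesis factors had medians of -0.88 and -1.11, below all 10000 matched random lists in either fraction; 24 of 66 were 2-fold lower in sub-polysomal and 38 in polysomal RNA, 19 in both, with 0 above 0 in polysomal RNA. The lowest in polysomal RNA were NOP13, a nucleolar RNA-binding protein gene (4.00-fold lower), and SDA1, needed to make the large subunit (3.81-fold lower); in sub-polysomal RNA they were the processing factor genes IMP4 (-1.70) and MPP10 (-1.70). Cytosolic ribosomal protein genes stood at -0.91 in sub-polysomal RNA (below all 10000 matched random lists; 37 of 81 2-fold lower, RPL36A at -2.36 the lowest) and -0.45 in polysomal RNA (at percentile 0.22; 3 2-fold lower). Under loess scaling these medians were -0.22 and -0.12, still below the random range. Of the 81, 52 had a probe set of the plain kind, meant to match 1 transcript, and 59 probe sets that name several genes including ribosomal protein genes were left out. Translation initiation factors were outside in polysomal RNA (-0.50, at percentile 0.43, 0 of 25 above 0 and 1 2-fold lower, TIF35 at -1.05) and inside in sub-polysomal RNA (-0.40).

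Respiration and mating genes were lower as well. Mitochondrial respiration genes had medians of -0.71 and -0.62 (below all 10000 matched random lists in either fraction), with 10 of 45 genes 2-fold lower in each and 2 and 1 higher. The NADH dehydrogenase gene NDE1 was lowest (-2.21 and -2.46), followed in polysomal RNA by the cytochrome oxidase gene COX5A (-1.52), while the succinyl-CoA ligase gene LSC2 was higher (2.11 and 1.33). The genes of mating type a, the type of this strain, had medians of -1.22 and -1.17 (percentiles 0.03 and 0.01): the a-factor gene MFA2 was at -3.62 and -2.45, against -0.31 and -0.23 for the other a-factor gene MFA1, whose polysomal value turned positive with hybridisation control scaling. The MFA1 probe sets, none of the plain kind, differed in sign in polysomal RNA (0.077 and -0.53). BAR1, which degrades the pheromone of the other mating type, was higher (1.84 and 1.90). Iron and zinc uptake genes were outside in polysomal RNA (-0.38, at percentile 1.37, 3 of 26 2-fold lower, led by the ferro-oxidase gene FET3 at -1.98) and inside in sub-polysomal RNA (-0.25); the polysomal call ended in 3 alternatives.

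The 12 genes lowest in both fractions, again among genes above every array's median, also had varied functions. PRY3, which encodes a cell wall protein, was 6.41-fold and 7.17-fold lower in the sub-polysomal and polysomal fraction, and MFA2 12.3-fold and 5.47-fold, with a sub-polysomal log2 change of -3.62 that was -2.83 under quantile scaling and also nearer 0 under loess scaling. The eisosome gene NCE102 (8.02-fold and 5.00-fold lower), the glucose transporter gene HXT6 (-2.44 and -2.67), the cell separation genes EGT2 (-2.59 and -2.31) and DSE4 (-1.99 and -1.96), and RNR1 of deoxynucleotide synthesis (-1.99 and -2.15) were also among them. HXT6 was read by 1 probe set that is not of the plain kind, so other transcripts may add to its value. The rest were NDE1, FET3 (-1.92 and -1.98), the membrane protein gene INA1 (-2.73 and -2.19), HMS2, a gene similar to heat shock factors (-2.18 and -1.92), and the phospholipase gene PLB2 (-1.91 and -2.44). Of common reference genes, ACT1 stood at -0.20 and -0.42 and the glycolytic gene PGK1 at 0.32 and -0.083. ACT1 turned positive in sub-polysomal RNA and PGK1 in polysomal RNA under quantile and loess scaling, PGK1 with hybridisation control scaling as well. The sub-polysomal change of PGK1 also moved under quantile and loess scaling, rose to as much as 1.25 and was past 2-fold in 2 alternatives.

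**Figure D2:**
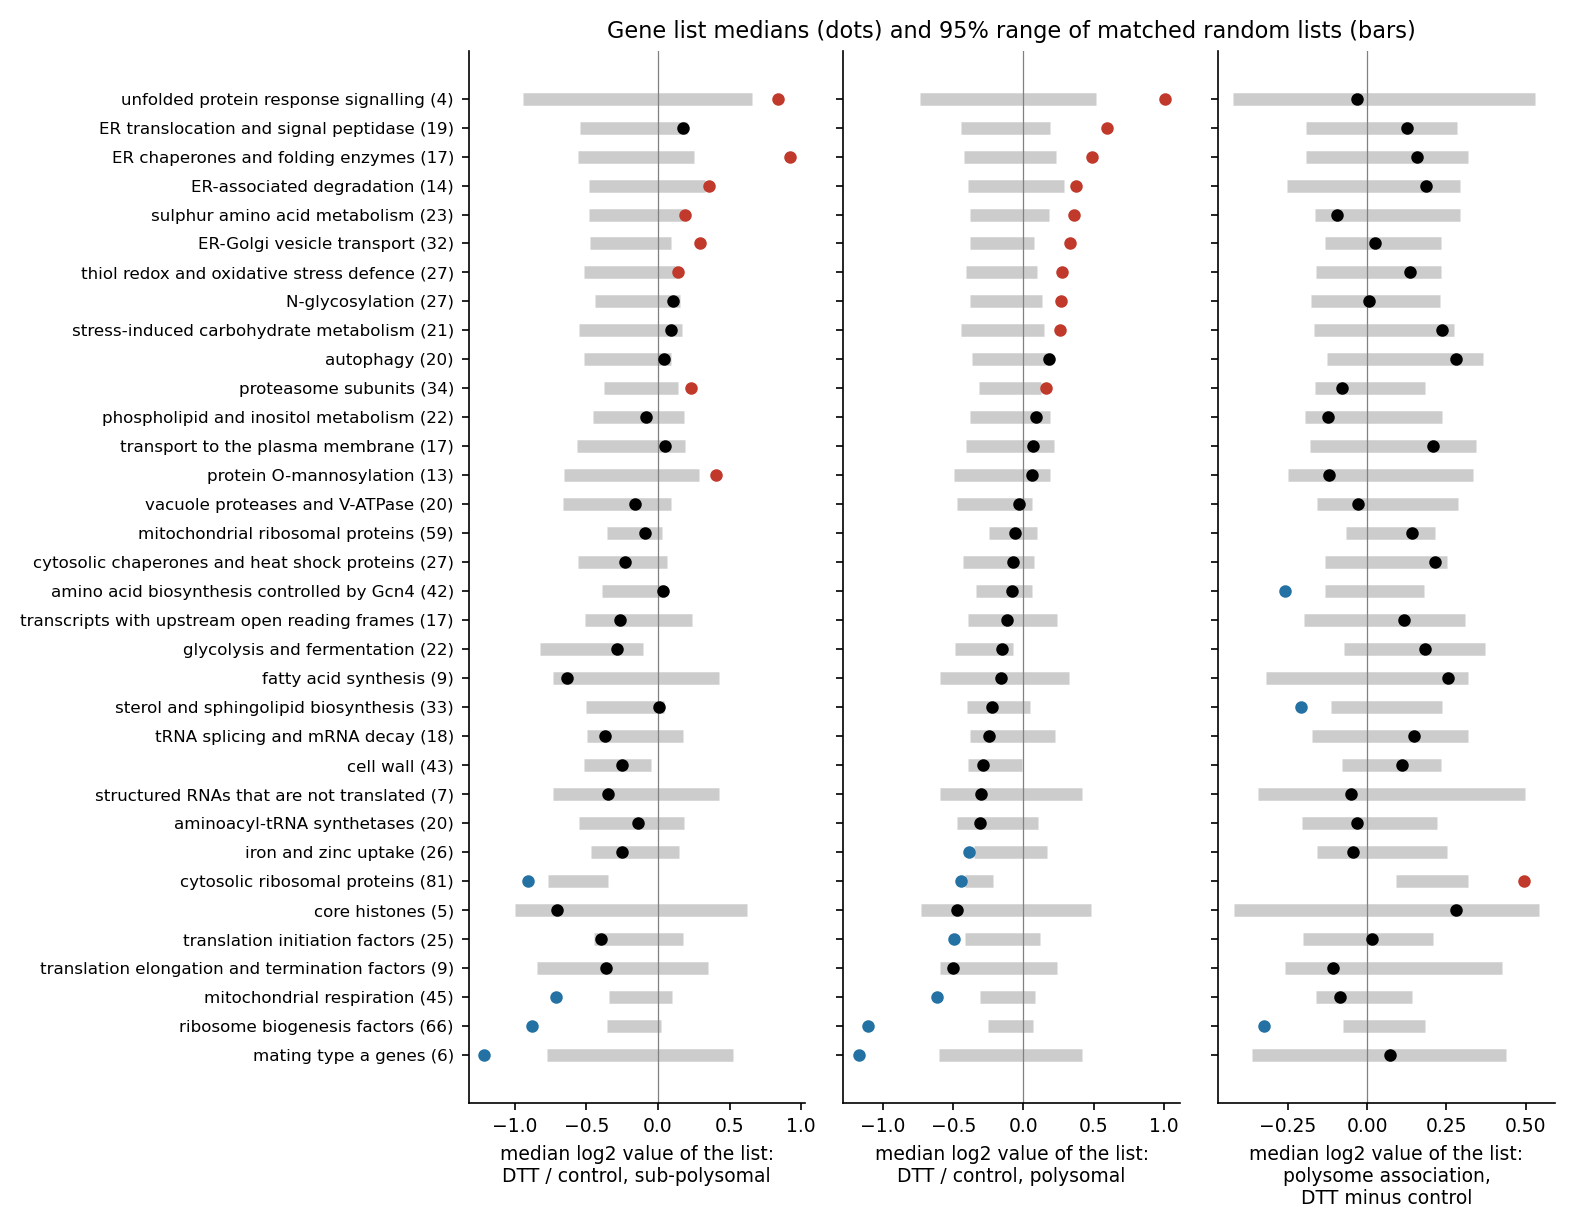
Median log2 value of each gene list (dots; members measured in brackets) in 3 panels, DTT against control in sub-polysomal RNA, in polysomal RNA, and polysome association in DTT minus control, with the 95% range of 10000 matched random lists as grey bars and lists outside it in red (high) or blue (low). ER chaperones (0.92 and 0.49) stand to the right and ribosome biogenesis (-0.88 and -1.11) to the left of the bars in both fractions, while 4 lists leave the bars for polysome association.

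Of 34 lists with at least 4 measured genes, 12 were outside in sub-polysomal and 16 in polysomal RNA, against 1.7 in each for lists of randomly drawn genes. Members of a list can move together, also through differences between single arrays. The 1.7 is therefore a yardstick and no test of an effect of DTT. Many lists lay inside the random range in both fractions, and of these glycolysis and fermentation, cell wall, phospholipid and inositol, fatty acid, mitochondrial ribosomal protein, vacuole, sterol and sphingolipid, aminoacyl-tRNA synthetase, Gcn4-controlled amino acid, cytosolic chaperone and upstream open reading frame genes changed sign under at least 1 other scaling. Their polysomal medians in that order were -0.15, -0.29, 0.090, -0.16, -0.061, -0.031, -0.22, -0.31, -0.078, -0.074 and -0.12. Autophagy genes (0.18), transport to the plasma membrane (0.071), core histones (-0.47), elongation and termination factors (-0.50), structured RNAs that are not translated (-0.30) and tRNA splicing and mRNA decay (-0.24) were inside too, with a sign that held under each scaling.

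Which transcripts sit in polysomes? In both treatments, transcripts of amino acid and respiratory enzymes, tRNA charging, cytosolic chaperones, the proteasome and the vacuole leaned to the polysomal fraction, and RNAs that are not translated to the sub-polysomal one. In control cells 279 genes were at least 2-fold higher in polysomal than sub-polysomal RNA and 255 at least 2-fold lower. The spread between probe sets around the all-gene median would give 25 and 37.1. In DTT-treated cells the counts were 188 and 149, against 8.00 and 1.50. Their balance moved with scaling, to 179 and 417 in control and 57 and 336 in DTT-treated cells without centring, and to 444 and 147, and 624 and 41, when centred on the hybridisation controls. The ratios of control and DTT-treated cells correlated across genes with Pearson r 0.733 and Spearman rho 0.720, and with no floor the Pearson r was 0.538. Ratios are relative to the median measured probe set. The all-gene median was -0.030 in control and 0.080 in DTT-treated cells, -0.20 and -0.16 without centring, and 0.15 and 0.43 when centred on the hybridisation controls.

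RNAs not translated by cytosolic ribosomes gave the clearest separation. Of 98 structured RNAs listed, such as small nucleolar RNAs, 7 were measured. They had median ratios of -1.90 in control and -1.69 in DTT-treated cells (below all 10000 matched random lists in either), with 6 of 7 2-fold lower in each. RDN37-1, a ribosomal RNA gene, was 5.23-fold lower in polysomal RNA of control cells, the small nucleolar RNA SNR70 3.74-fold and the mitochondrial COX1, read by ribosomes inside that organelle, 4.06-fold. Which part of the ribosomal RNA the RDN37-1 probe sets read is not known here. Of genes above every array's median, also lowest in control cells were OST4, a very small subunit of oligosaccharyltransferase (-2.19 in control and -1.33 in DTT-treated cells), the membrane protein gene BRE4 (-2.31 and -1.11), the allantoate permease gene DAL5 (-1.93 and -1.60), the cyclin gene PCL1 (-1.73 and -1.16) and the RNA decay gene LSM6 (-1.76 and 0.21). The control ratio of DAL5 moved with no floor and with the floor in 1 fraction, to as little as -0.97.

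Many of the groups leaning to polysomes were outside in both treatments. In control cells the medians outside the random range were 0.81 for aminoacyl-tRNA synthetases (7 of 20 genes 2-fold higher), 0.80 for Gcn4-controlled amino acid genes (17 of 42), 0.78 for vacuole genes (6 of 20), 0.70 for respiration (13 of 45), 0.67 for cytosolic chaperones (7 of 27), 0.65 for the proteasome (6 of 34), 0.53 for redox genes (5 of 27), 0.52 for sterol and sphingolipid genes (2 of 33), 0.51 for N-glycosylation (3 of 27) and 0.49 for ER to Golgi transport (8 of 32). In DTT-treated cells they were 0.94 for cytosolic chaperones, 0.88 for the synthetases, 0.78 for stress-induced carbohydrate genes, 0.74 for vacuole genes, 0.67 for redox genes, 0.61 for the proteasome, 0.60 for ER to Golgi transport, 0.57 for respiration, 0.54 for transport to the plasma membrane and 0.52 for amino acid genes. In all 13 lists were outside in control and 16 in DTT-treated cells, against 1.7 for lists of randomly drawn genes. The control calls of N-glycosylation, ER to Golgi transport and sterol genes and the DTT call of transport to the plasma membrane ended with a floor at the 60th percentile. That of N-glycosylation also ended with the offset and the list mean, that of sterol genes with the floor in 1 fraction and with plain probe sets only, and that of the plasma membrane under quantile and loess scaling. Examples in control cells are the asparaginyl-tRNA synthetase gene DED81 (1.77), the asparagine synthetase gene ASN2 (2.12), the vacuolar ATPase gene VMA2 (1.42), the fumarase gene FUM1 (1.95) and the ribosome-bound chaperone gene SSZ1 (1.48).

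Groups low in polysomes against random lists of like brightness included transcripts for ribosomes. Mitochondrial ribosomal proteins had medians of -0.31 in control and -0.23 in DTT-treated cells (percentiles 1.54 and 0.50), with 6 and 0 of 59 2-fold lower; with no floor the control call ended (0.016). Cytosolic ribosomal proteins stood at -0.15 in control cells (below all 10000 matched random lists). In DTT-treated cells they stood at 0.31, with 75 of 81 above 0, under the matched random range of 0.33 to 0.47 (at percentile 0.29). Those random lists could hold ribosomal protein genes themselves. That DTT value turned negative under quantile (-0.086) and loess (-0.14) scaling, and against unmatched random lists it lay at percentile 99.7, on the high side. The control call of cytosolic ribosomal proteins ended against unmatched random lists. Ribosome biogenesis was -0.57 in DTT-treated cells (below all 10000 matched random lists, 11 of 66 2-fold lower, UTP18 at -1.76 and NOG1 at -1.44), and -0.15 in control cells (at percentile 4.44). Transcripts with described upstream open reading frames, such as CPA1 (-1.60), had a DTT ratio of -0.34 (at percentile 0.76, 3 of 17 2-fold lower) and iron and zinc genes -0.26 (at percentile 0.66, 2 of 26, ZRT2 at -1.35); in control cells their medians were -0.34 and -0.28, inside. GCN4, with its known upstream frames, stood at -0.84 and -0.69. Hybridisation control scaling made several of these medians positive, but it adds the same amount to every gene and left their place among random lists as it was.

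The 8 genes highest in control polysomes, of those above every array's median, are given with both ratios. They were picked for the control ratio, so a smaller ratio in DTT-treated cells follows in part from that choice. LAT1, of the pyruvate dehydrogenase complex, was 6.05-fold higher in polysomal RNA of control cells and 2.17-fold in DTT-treated cells, the arabinose dehydrogenase gene ARA1 6.02-fold and 2.49-fold, and the beta-tubulin gene TUB2 5.16-fold and 2.11-fold. The others were the aromatic aminotransferase gene ARO8 (2.30 and 1.21), the RNA-binding protein gene SBP1 (2.29 and 1.05), ASN2 (2.12 and 0.93), the ER proline isomerase gene CPR5 (1.98 and 1.04) and FUM1 (1.95 and 0.75). Reference genes leaned the same way, ACT1 with 0.69 and 0.46, and PGK1 with 0.62 and 0.21, the last negative without centring and under quantile and loess scaling. The control probe sets for the 3' end, middle and 5' end of ACT1 had larger ratios in DTT-treated cells. They stood at 0.36, 0.80 and 1.07 in control and 0.78, 1.08 and 1.14 in DTT-treated cells.

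Did DTT move transcripts onto or off polysomes? Few transcripts differed relative to the median measured probe set: 96.6% of genes kept a polysomal to sub-polysomal ratio within 2-fold of control. A move onto or off polysomes shared by most transcripts could not be seen, because each array was centred on its median. HAC1 and ERO1, also higher in amount, leaned more to polysomes by over 2-fold, HAC1 in 7 and ERO1 in 10 of 11 alternatives. However, most genes past that limit on the higher side cannot be told from measurement spread around the all-gene median, which lay above 0. As groups, cytosolic ribosomal protein transcripts leaned more to polysomes, and those for ribosome biogenesis, amino acid synthesis and sterols less.

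**Figure D3:**
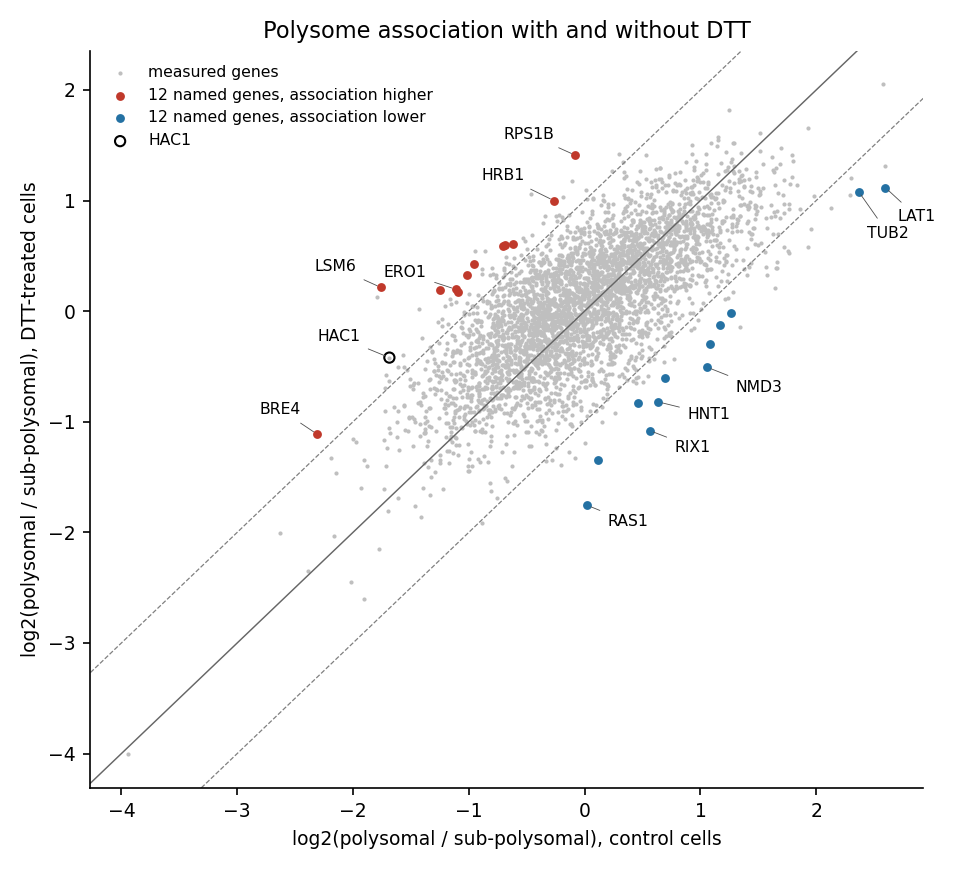
Each grey point is 1 of 3923 genes, with log2 polysomal over sub-polysomal RNA in control cells on the horizontal axis and in DTT-treated cells on the vertical axis; red and blue points are the 12 named genes with the highest and lowest change, the solid line marks equal ratios and dashed lines 2-fold. Most genes lie between the dashed lines (96.6%), with HAC1 (-1.69 and -0.42) above them and RAS1 (0.021 and -1.75) below.

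The 2-fold limit took in 78 genes with higher and 57 with lower polysome association in DTT. The spread between probe sets of a gene, set around the all-gene median, would put 66.0 and 24.6 past it. The higher number on the higher side comes from that median lying above 0, and a spread around 0 was not computed. Most single genes past the limit on the higher side, and many on the lower, therefore cannot be told from measurement spread and that offset together. The all-gene median of the change was 0.081, or 0.25 when centred on the hybridisation controls. The counts moved with the scaling, the floor and the limit. The balance of higher to lower reversed under loess (56 and 114) and quantile scaling (77 and 113), without centring (54 and 93) and with no floor (333 and 404), against 185 and 30 when centred on the hybridisation controls. At a 3-fold limit 2 and 2 genes were left: LSM6 and the transcription factor gene TYE7 (1.92) on the higher side and RAS1 and RIX1 on the lower side, TYE7 being chosen after its value was seen. Of the 78 genes 34 were 2-fold lower in sub-polysomal RNA and 13 were 2-fold higher in polysomal RNA, and of the 57 genes 22 were 2-fold higher in sub-polysomal and 12 lower in polysomal RNA.

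HAC1 had a control ratio of -1.69 (3.22-fold lower in polysomes; -0.52 with no floor) and a DTT ratio of -0.42, a change of 1.27 (2.40-fold). Its 3 probe sets above the floor gave 0.82, 1.26 and 1.72, none of them of the plain kind, and over 11 alternatives the change ran from 0.17 to 1.44 and stayed past 2-fold in 7. With no floor a probe set enters that read 1.2, 4.1, 3.2 and 0.9 in control sub-polysomal, control polysomal, DTT sub-polysomal and DTT polysomal RNA. Another, at 42.4, 17.1, 220.8 and 193.1, was under the floor on the control polysomal array only. Control polysomal intensities were 67.7, 18.2 and 48.6 for these probe sets, with that array's floor at 17.6, against 377.3, 93.3 and 401.3 on the DTT polysomal array. ERO1 had a like profile, with a control ratio of -1.11 and a change of 1.31 (2.48-fold), past 2-fold in 10 of 11 alternatives. Its DTT ratio of 0.20 was negative without centring (-0.044) and under loess scaling (-0.029).

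**Figure D4:**
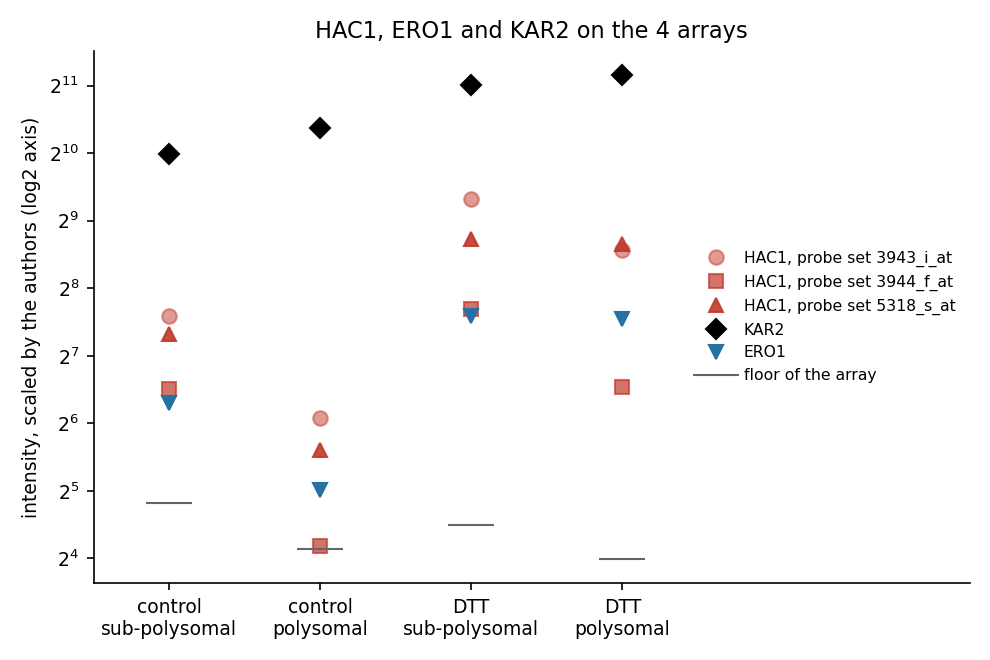
Intensity scaled by the authors (log2 axis) of 3 HAC1 probe sets, ERO1 and KAR2 on the 4 arrays, with each array's floor as a grey line; each symbol is 1 value of 1 array. The HAC1 probe sets read 18.2 to 67.7 in control polysomal RNA and 93.3 to 401.3 in DTT polysomal RNA, and KAR2 lay far above the floor on every array.

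Other ER genes fixed in advance showed no common direction of association. The chaperones and folding enzymes had a median change of 0.16 (at percentile 74.2), with 1 of 17 members 2-fold higher (ERO1); it turned negative under quantile (-0.10) and loess (-0.16) scaling. DER1 (1.09), HRD1 (0.90) and SCJ1 (0.69) leaned to polysomes, LHS1 (0.12) and EUG1 (0.23) were positive but turned negative under quantile and loess scaling, and KAR2 (-0.16, positive at 0.013 with hybridisation control scaling), PDI1 (-0.18) and FPR2 (-0.44) were negative. The DER1 value rests on a probe set with 29.4 in control polysomal RNA, close to the floor, and with no floor the gene's other probe set took its change to -1.37. Degradation (0.19), translocation (0.13), N-glycosylation (0.0065), ER to Golgi transport (0.024), O-mannosylation (-0.12) and unfolded protein response signalling genes (-0.032) were all inside the random range, the last 4 with signs that flipped under other scalings.

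As a set, genes higher in both fractions did not lean more to polysomes. The 111 genes higher in both fractions had a median change of -0.052 and the 181 lower ones -0.010. Of the 111, 3 were also 2-fold higher in association. That count cannot be judged against the 2.2 of independent calls, because the association change is the difference of the 2 changes used to pick the 111. The medians of both sets are tied to the way they were picked for the same reason. The 3 genes were HAC1, ERO1 and GSC2, a glucan synthase gene for the stressed cell wall (1.52). Another 4 were 2-fold lower: CRH1, which links chitin to glucan (-1.27), GPI16, of GPI anchor transfer (-1.25), OPI3, of phosphatidylcholine synthesis (-1.10), and COS8 (-1.02). Of the 181, 3 were 2-fold higher in association, MFA2 (1.16), RPL36A (1.02) and the mating type switching gene HO (1.29), and 1 lower, the acid phosphatase gene PHO3 (-1.29). GPI16, COS8 and HO were chosen after their values were seen.

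Cytosolic ribosomal protein transcripts leaned more to polysomes as a group. Their median change in association was 0.49 (1.41-fold; above all 10000 matched random lists), with 68 of 81 above 0, 7 2-fold higher and 0 2-fold lower. RPS1B (1.49), whose probe sets are not of the plain kind, and RPS28A (1.15) were highest, RPL22B (-0.86) and RPL7A (-0.46) lowest. The random range was itself above 0 (0.093 to 0.32), with equally bright genes as a whole lying higher, and the median was 0.14 under loess scaling, still above all matched random lists, and 0.066 under quantile scaling. The sub-polysomal change was -0.91 and the polysomal change -0.45, so that the list was low in the pair of arrays without the control sub-polysomal array.

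Ribosome biogenesis transcripts shifted the other way, with a median of -0.32 (1.25-fold lower; below all 10000 matched random lists), 52 of 66 below 0, 4 2-fold lower and 1 higher. NSR1, a nucleolin-like gene (-1.15), and the helicase gene RRP3 (-1.13) were lowest, PWP2 (1.06) highest. Gcn4-controlled amino acid genes stood at -0.26 (at percentile 0.02, 31 of 42 below 0 and 1 2-fold lower, ASN2 at -1.19 and ILV1 at -0.94), and sterol and sphingolipid genes at -0.21 (at percentile 0.16, 25 of 33 below 0 and 0 2-fold lower, TSC10 at -0.85 and ERG7 at -0.78). These 4 of 34 lists were outside, against 1.7 for lists of randomly drawn genes, whose members do not move together as those of a list can. Each stayed outside on the same side in all 14 alternatives that recompute it, of which 3 only move each array's centre and could not change the call. Their order by size did not hold: under loess scaling medians were -0.22 for biogenesis, -0.33 for amino acid and -0.32 for sterol genes, each larger in size than the 0.14 of ribosomal proteins. The amino acid and sterol genes were inside the random range both in sub-polysomal RNA (0.035 and 0.0082) and in polysomal RNA (-0.078 and -0.22), the sub-polysomal medians close to its upper edge at percentiles 96.8 and 95.8.

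Single genes at the extremes, ranked here among genes above every array's median, came from many pathways. Genes outside that set, such as TYE7 (1.92) and GSC2 (1.52), are not ranked. Beside ERO1, the 12 with the largest increase were LSM6 (1.97), RPS1B, IRC21, a cytochrome b5-like gene (1.44), ROX1, the repressor of hypoxic genes (1.39), the glucanase gene EXG2 (1.34), the coactivator gene SUB1 (1.29), RRN5, of RNA polymerase I initiation (1.29, from 1 of 3 probe sets, below 2-fold in 3 settings of the floor and 0.39 with no floor), the DNA repair gene NTG2 (1.27), HRB1, of mRNA export (1.26), BRE5, a deubiquitinase cofactor (1.22), and BRE4 (1.20). Of these, LSM6 had a polysomal change of 0.056 and a sub-polysomal change of -1.92, while IRC21 had 1.21 and -0.23.

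The largest decreases, among the same set of genes, were led by the signalling GTPase gene RAS1 (-1.78, 3.43-fold). RIX1, of large subunit processing, stood at -1.64, NMD3, its export adaptor, at -1.56, and RMT2, a methyltransferase of ribosomal protein, at -1.38. The others were LAT1 (-1.48), the nucleotide hydrolase gene HNT1 (-1.46, with -1.44 and -1.47 from its probe sets), the zinc transporter gene ZRT2 (-1.46), the cell wall protein gene TOH1 (-1.30), the purine synthesis gene ADE13 (-1.30), PHO3 (-1.29, within 2-fold under loess scaling and -0.85 under quantile scaling), TUB2 (-1.29) and the vesicle tethering gene BET3 (-1.28). RAS1 was lower in polysomal RNA (-2.63) and less so in sub-polysomal RNA (-0.85); LAT1 differed by 1.58 in sub-polysomal and 0.097 in polysomal RNA.

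Other genes fixed in advance are given here for reference. GCN4 had a change of 0.15, negative under quantile and loess scaling, and the transcripts with upstream open reading frames a median of 0.12, negative under loess scaling. FKS1, the glucan synthase gene of growing cells, stood at 0.33, ACT1 at -0.23, PGK1 at -0.41, MFA1 at 0.083, HIS3 at -0.28 and the sulphite reductase gene MET5 at 0.85. The control probe sets of ACT1 went the other way, at 0.42, 0.28 and 0.070 for its 3' end, middle and 5' end. All remaining lists were inside the random range for association, with medians from -0.12 for phospholipid and inositol genes (positive with hybridisation control scaling) to 0.28 for autophagy and 0.28 for core histones; a-type mating genes had 0.071 and structured RNAs -0.051, which turned positive under quantile and hybridisation control scaling.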

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

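Of the tests in this part, the one on the control sub-polysomal array was chosen after the result was seen; the others were set before. With 1 array per group, none of the differences named here was tested against replicates.

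For 11 named genes the polysomal to sub-polysomal ratio had opposite signs in control and DTT-treated cells, each larger in size than the SD between probe sets (0.41 and 0.32), with a change of at least 2-fold between them, which is why they are listed; the differences were not tested. The change in association was 1.39 for the hypoxic repressor ROX1, 1.34 for the glucanase gene EXG2, 1.29 for the coactivator gene SUB1, 1.29 for RRN5 of RNA polymerase I initiation (0.385 with no floor), 1.22 for the deubiquitinase cofactor BRE5 and 1.09 for DER1 of ER-associated degradation (-1.369 with no floor). It was -1.64 and -1.56 for the ribosome assembly genes RIX1 and NMD3, -1.46 for the nucleotide hydrolase gene HNT1, -1.30 for the purine gene ADE13 and -1.29 for the acid phosphatase gene PHO3 (-0.854 under quantile scaling). Probe sets that name no gene are data outside the comparisons of genes. Of these 366 lay above the floor on all arrays, 82 were at least 2-fold higher with DTT in both fractions and 20 lower. The highest of them was at 2.57 in sub-polysomal and 2.50 in polysomal RNA, and the next at 2.32 and 2.45; these differences were not tested, and the tables used here do not say what the probe sets measure.

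Cytosolic ribosomal protein transcripts leaned more to polysomes with DTT, by a median of 0.495. Brightness of their probe sets is argued against as the whole cause, within a coarse match. Equally bright genes that encode no ribosomal protein had a median of 0.140 (95% range 0.064 to 0.295). They were drawn in 5 brightness bins, the smallest with 16 genes. After loess scaling the list stood at 0.141, above all matched random lists, although most of the size went with that correction. Under quantile scaling the list stood at 0.066. The control sub-polysomal array stays open as a source. In the polysomal pair, which leaves it out, the list lay at -0.447, below its random range and opposite to the shift, and the shift came from a larger loss in sub-polysomal RNA (-0.908). A change in the translation of these transcripts with DTT, the biological explanation that the design offers, stays open and untested, since the array and the group cannot be told apart.

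Ribosome biogenesis transcripts leaned less to polysomes, by a median of -0.324. Signals close to the floor are argued against, since the 31 members at least 4 times above it had a median of -0.302 (random range -0.126 to 0.213). The loss of transcript alone is argued against as well: other genes with a like loss had a median of 0.143 (0.014 to 0.266). In DTT-treated cells, without any control array, the group was low in polysomes (-0.57, below all 10000 matched random lists), against -0.15 in control cells. Reduced loading of these transcripts with DTT is a candidate explanation and remains a hypothesis, with differences between single hybridisations open.

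HAC1 leaned more to polysomes by 1.27. The 111 genes higher with DTT in both fractions had a median of -0.052, and HAC1 lay at percentile 97.3 of them, so its change was not shared by that set. The set was picked by the 2 changes whose difference is the association change. It therefore cannot decide whether transcripts higher with DTT shifted in general. Low signal on the control polysomal array stays open: the brightest probe set alone gave 0.821, under 2-fold, while an offset of each array's 10th percentile left 1.22. The probe sets may also differ in which part of the transcript they read, which was not tested because their positions are not in the tables used here. Release of HAC1 from its known translational block by splicing is a hypothesis that was not tested, as it is not known here which probe sets read spliced or unspliced RNA.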

How the results depend on the processing

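Centring on the measured genes and on the hybridisation controls was chosen after the data were seen; the other 14 alternatives were planned. The 4 lists outside for the change in polysome association stayed outside on the same side in every alternative that recomputed them, though 3 of these only move each array's centre and cannot change such a call. Of 2370 list medians under alternatives, 2272 kept their place above, inside or below the random range. Another 69 moved outside it, 28 moved inside and 1 reversed, from the low to the high side. These counts follow the place among random lists, so a median that changed sign but kept its place is among the 2272. Of 1997 values of named genes 1931 stayed within the spread between probe sets, 65 moved and 1 reversed, and of 194 counts 125 stayed within 1.5 times and 69 moved. Scalings that moved the all-gene median by over 0.1 were hybridisation control scaling (for the change in association to 0.254 from 0.081), no centring and loess, the last in the fractions. No paired analysis was possible because the labels give no replicate numbers and each group holds 1 array, so that leaving an array out would empty its group.

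As reported, the genes higher and lower by at least 2-fold were 78 and 57 for association (57.8% higher), 279 and 255 for the control ratio (52.2% higher), 188 and 149 for the DTT ratio (55.8% higher), 111 and 181 for both fractions (38.0% higher), 170 and 276 for polysomal (38.1% higher), 223 and 437 for sub-polysomal (33.8% higher). Where a count moved by over 1.5 times or the share of higher genes by over 10 points, the counts in the same order follow, with the share where it moved; the cause was not tested, except that a looser limit, a lower floor or none lets in more genes and a stricter one fewer. Without centring they were 54 and 93 for association (36.7% higher), 179 and 417 for the control ratio (30.0% higher), 57 and 336 for the DTT ratio (14.5% higher), 271 and 304 for sub-polysomal (47.1% higher). With quantile normalization they were 77 and 113 for association (40.5% higher), 101 and 133 for the DTT ratio (43.2% higher), 310 and 390 for sub-polysomal (44.3% higher). With loess scaling they were 56 and 114 for association (32.9% higher), 97 and 149 for the DTT ratio (39.4% higher), 142 and 111 for both fractions (56.1% higher), 215 and 226 for polysomal (48.8% higher), 331 and 195 for sub-polysomal (62.9% higher). With a floor at the 25th percentile they were 178 and 99 for association, 416 and 387 for the control ratio. With a floor at the 60th percentile they were 40 and 31 for association, 119 and 183 for the control ratio (39.4% higher), 63 and 96 for the DTT ratio (39.6% higher), 58 and 108 for both fractions, 83 and 157 for polysomal, 115 and 268 for sub-polysomal. With no floor they were 333 and 404 for association (45.2% higher), 909 and 464 for the control ratio (66.2% higher), 513 and 366 for the DTT ratio, 237 and 261 for both fractions, 439 and 536 for polysomal, 634 and 561 for sub-polysomal (53.1% higher). Centred on the measured genes they were 261 and 331 for sub-polysomal (44.1% higher). Centred on the hybridisation controls they were 185 and 30 for association (86.0% higher), 444 and 147 for the control ratio (75.1% higher), 624 and 41 for the DTT ratio (93.8% higher), 149 and 115 for both fractions (56.4% higher), 292 and 164 for polysomal (64.0% higher). At a 1.5-fold limit they were 532 and 358 for association, 755 and 779 for the control ratio, 734 and 553 for the DTT ratio, 283 and 541 for both fractions, 449 and 755 for polysomal, 542 and 1067 for sub-polysomal. At a 3-fold limit they were 2 and 2 for association, 46 and 36 for the control ratio, 4 and 20 for the DTT ratio, 44 and 35 for both fractions, 68 and 61 for polysomal, 83 and 83 for sub-polysomal. The correlation of the ratios (0.733) was 0.538 with no floor. The list median counted as reversed was the ribosomal protein ratio in DTT-treated cells (0.309, low among matched lists), at percentile 99.73 among unmatched lists. The gene value counted as reversed was the change in association of DER1, 1.09 as reported and -1.369 with no floor, where a second probe set enters that read 1.0 on the control sub-polysomal array. Other gene values changed sign without being past 2-fold on both sides, such as the control ratio of DER1, -0.61 as reported and 1.81 with no floor.

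The number of genes lying a given distance over the floor limits every count: with no floor 5653 genes enter, with intensities down to 0, and with a floor at the 60th percentile 2388. Genes with weak signal, such as IRE1 and INO1, give no ratio here.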

Other observations

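The tests on patterns were all set out with the differences above; the values here were read without a hypothesis. Cell wall genes went both ways with DTT, and the list's medians (-0.25 and -0.29 in sub-polysomal and polysomal RNA) lay inside the random range, with signs that turned positive under quantile and loess scaling. Of 43 genes 5 were 2-fold higher and 12 lower in sub-polysomal RNA, and 5 and 7 in polysomal RNA. The stress-type glucan synthase gene GSC2 (2.06 and 3.59), the crosslinking enzyme gene CRH1 (2.57 and 1.30) and the surface protease gene YPS3 (1.81 and 2.16) were higher, while the mannoprotein genes TIP1 (-2.10 and -1.89) and CCW12 (-1.94 and -0.87) and the glucan remodelling gene GAS3 (-1.79 and -1.74) were lower. FKS1, the synthase of growing cells, stood at -0.34 and -0.020, its sub-polysomal value being -0.879 with plain probe sets only or its brightest probe set and its polysomal value turning positive under every other scaling.

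In phospholipid and inositol metabolism OPI3, of phosphatidylcholine synthesis, was higher (2.27 and 1.17) and the CTP synthase gene URA7 lower in polysomal RNA (-1.43). Fatty acid genes held 3 of 9 members 2-fold lower in sub-polysomal RNA, the elongase gene ELO1 (-1.43) first. In glycolysis the glucose transporter gene HXT1 stood at 1.15 and 1.27 and the enolase gene ENO1 at 1.21 and 0.70. The vacuolar protease gene PRB1 was higher (2.23 and 1.49), as was the autophagy gene ATG5 (1.58 and 1.88), and the histone gene HTB2 was lower (-1.72 and -0.99). The heat shock factor gene HSF1 was higher (1.64 and 1.32), while HSP26, a small heat shock protein gene, was lower (-1.76 and -1.16). TIS11, which speeds decay of iron-linked mRNAs, was higher (2.06 and 1.85) where FET3 was lower.

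Genes of other cell types and markers of the strain were read out as well. Of 6 mating type alpha genes 1 was measured, SAG1, which read 50.2, 31.0, 64.1 and 46.1 in control sub-polysomal, control polysomal, DTT sub-polysomal and DTT polysomal RNA, and of 18 meiosis genes 1, IME1, which read 39.4, 61.2, 37.8 and 43.3. Of the 4 auxotrophic markers HIS3 was measured, with 186.1, 207.8, 182.7 and 160.2 from its brighter probe set. URA3 read 1.2, 0.9, 0.3 and 0.3, LEU2 17.6, 17.5, 6.6 and 9.0 from its brightest probe set and MET17 2.9, 7.1, 0.4 and 0.9, none above the floor. The labels call MET5 deleted, where the usual genotype of this strain lacks MET17; MET5 read 184.5, 96.7, 165.8 and 149.5, above the floor on all 4 arrays.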
